A study of Mus musculus with 85 samples.

How the data were processed

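RNA sequencing of mouse preimplantation embryos was analysed from the series' processed table. According to the submitters' processing notes, reads were aligned with STAR 2.6.1d to mm10. The deposited values are counts scaled to a fixed total (CPM) with an offset of 1e-04 added, for 37394 genes in 91 columns. The unit was checked on the columns, which have nearly the same sum. Of the columns, 85 were matched to samples by their names and 6 were not matched and were not used. Another 26 table entries whose names are numbers were left out (between 0.046% and 0.194% of the values of a library). Of the remaining symbols, 37145 matched GENCODE vM21 (GRCm38). Tdh had a missing value in library 1 of the standard morulae.

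Read depth was inferred from the smallest step between values and lay between 10.2 and 42.6 M reads (median 19.6 M). At a level of 1 CPM, counting alone gives a relative SD of 31.3% in the shallowest library and 15.3% in the deepest. In 138 pairs of replicates, squared differences were 2.32 to 41.6 times those from counting. Whole reads could not be recovered: of the values of at most 20 reads, 69.7% to 78.2% per library lay within 0.1 of a whole number. The tests planned for counts were therefore not run, and the plan's fallback for CPM was used.

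Groups were taken from the labels (21 groups by stage, age and medium). Values were analysed as log2(CPM + 1) for genes above 1 CPM in at least 3 libraries of a fit, with limma 3.58.1 in R 4.3.3 (moderated t with a mean trend, Benjamini-Hochberg threshold 0.05). Separate fits held the standard groups, the groups at 34 to 55 h, those at 78 h and those at 114 h, and the interactions held the groups they compare. There were 18 comparisons and 11 steps between neighbouring standard ages. The comparisons, the 26 gene lists, the rule for naming genes and the first set of alternatives were fixed before the data were examined. Gene lists were tested with camera at a preset correlation of 0.01. In 116 of 465 list tests, adjusting over the list alone gave another count of members. Stage position is the projection of a library on the line between the means of the end groups, over genes that differ between them at least 2-fold, and was compared by exact two-sided permutation. It used log2(CPM + 1) without further scaling and was not computed again under the alternative scalings, so a shift of all genes can move it. Other calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

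Genes to name were the 6 largest rises and 6 largest falls with at least 20 CPM in the higher group and no overlap between groups, and up to 3 members of each list that passed camera or had at least 3 members past the threshold. In media comparisons, 12 genes of pyruvate, lactate and glucose handling and the MYC family were added. The genes printed were chosen from these for a known role, and preferably among those whose call held under every alternative. Lists were of pathways, organelle and cell cycle functions, cell lineages, and markers of cumulus, sperm and blood cells. The procedure was tested on simulated data, where 173, 177 and 168 of 200 altered genes were recovered with 7, 12 and 11 false calls. Alternatives were a pseudocount of 0.1, no filter, only the groups compared, a replicate block, leaving out each library, and an estimated correlation for lists. Median-ratio scaling, quantile scaling, removal of a trend with gene length, and leaving out standard morula libraries 1 and 2 were chosen after seeing the data.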

Results

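RNA was measured by sequencing in 85 libraries of mouse preimplantation embryos of the B6C3F1/J strain, in 21 groups. The Smart-seq2 method was used, which primes cDNA at the poly(A) tail and amplifies it whole. The standard culture medium was KSOM, in which lactate was at 5 mM and pyruvate and glucose were each at 0.2 mM. Ages are hours after the hCG injection that sets the time of ovulation. In standard medium, the 2-cell groups, with their ages and read depths (M reads), were early 2-cell (3 libraries, 34 h, 13.4 to 16.6), mid 2-cell (4 libraries, 42 h, 11.3 to 18.7), late 2-cell (3 libraries, 48 h, 19.9 to 27.9) and very late 2-cell (3 libraries, 52 h, 11.6 to 19.6). The 4-cell and 8-cell groups were early 4-cell (4 libraries, 55 h, 27.1 to 42.6), late 4-cell (4 libraries, 62 h, 15.9 to 32.7), early 8-cell (3 libraries, 66 h, 13.7 to 33.4) and late 8-cell (2 libraries, 74 h, 30.5 to 32). The later groups were morula (6 libraries, 78 h, 17.9 to 34.1), early 16-cell (5 libraries, 80 h, 17.2 to 28), early 32-cell (4 libraries, 90 h, 19 to 26.8) and blastocyst (4 libraries, 114 h, 24.7 to 32.6). Medium without pyruvate gave 2-cell embryos at 42 h (4 libraries, 17 to 23.8) and 48 h (5, 14.9 to 25). It gave them at 52 h (4, 10.4 to 19.6) and 55 h (4, 10.2 to 18.7). It also gave morulae (5, 34 to 38) and blastocysts (5, 10.5 to 17.1). Medium without lactate gave morulae (5, 13.4 to 22.6) and blastocysts (4, 17.4 to 28.2). A last group of morulae had no pyruvate and 20 nM of KY-PYR-9, a compound the labels call a MYC inhibitor (4, 15.9 to 21.6). Between 11347 and 17438 genes per library lay above 1 CPM (counts scaled to a fixed total per library). The number of embryos or cultures behind a library was not stated, so p-values measure only the spread between these libraries.

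Levels below are CPM as mean ± SD over the libraries of a group, with the first-named group first and the group sizes given above. Log2 changes are on the log2(CPM + 1) scale, which understates changes of genes near or below 1 CPM. All tests were two-sided, and gene list tests (camera) were competitive, setting a list against all other genes. A second p-value, with the correlation between genes estimated, is given where it ended the call. The 3 scalings below are, in order, median-ratio, quantile and removal of the length trend. They align libraries, so they cannot test a shift of all genes. Genes named among the largest rises and falls had groups that did not overlap in any library, so every library showed the direction. Gene positions refer to GRCm38 (mm10) as annotated in GENCODE vM21.

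Groups differed in how much of the RNA came from few genes. The 100 highest genes held 50.4 ± 2.0% (SD, n = 3) of all values in early 2-cell embryos and 25.7 ± 1.71% (SD, n = 3) in late 2-cell embryos. They held 42.4 ± 1.74% (SD, n = 4) in standard blastocysts. Blastocysts without pyruvate had 24.5 ± 0.794% (SD, n = 5), and those without lactate 41.5 ± 1.01% (SD, n = 4). Standard morulae had 27.6 ± 4.07% (SD, n = 6), with libraries 1 and 2 apart from the others at 34.8% and 30.2%. Morulae without pyruvate had 21.8 ± 1.12% (SD, n = 5), and with the inhibitor 36.4 ± 1.3% (SD, n = 4). Mitochondrially encoded genes held 3.58 ± 2.52% (SD, n = 6) in standard morulae and 1.04 ± 0.827% (SD, n = 5) without pyruvate. With the inhibitor the share was 6.04 ± 2.11% (SD, n = 4), and 11.7 ± 2.08% (SD, n = 4) in blastocysts without lactate.

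**Figure D1:**
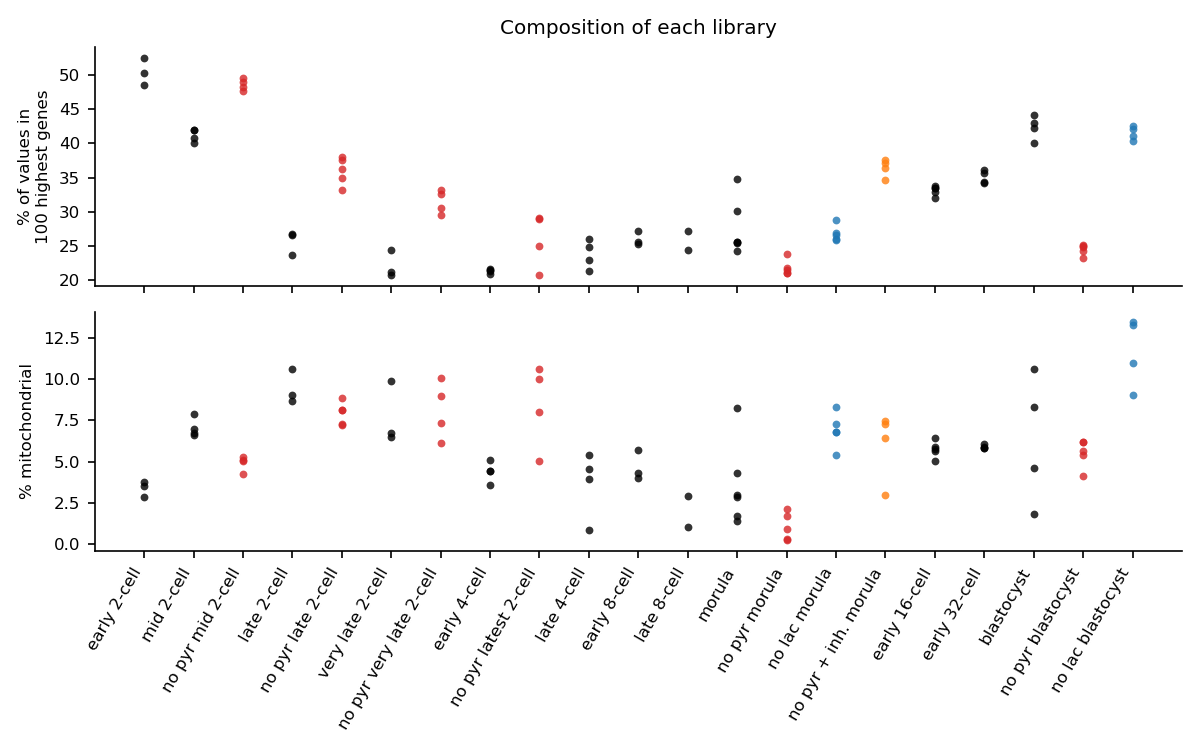
Share of all CPM values in the 100 highest genes (upper axis, %) and in mitochondrially encoded genes (lower axis, %), a point per library, by group. Standard blastocysts lay between 40.03% and 44.2% on the upper axis and blastocysts without pyruvate between 23.2% and 25.2%.

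Late 2-cell embryos (48 h) were compared with early 2-cell embryos (34 h) to describe the transcripts that appear when the embryonic genome is switched on. The largest rises included Timd2 (a ferritin-binding surface receptor, 1259 ± 117 against 2.69 ± 1.91), Prps1 (which makes the ribose donor of nucleotide synthesis, 3087 ± 113 against 9.69 ± 3.88) and Pdxk (pyridoxal kinase, 651 ± 55.6 against 1.37 ± 1.47). Timd2 lies on chromosome 11, 46668960 to 46707061. The largest falls included Oas1e (of the oligoadenylate synthetase family, 52.5 ± 3.32 against 6119 ± 1752), Rgs2 (a regulator of G protein signalling, 31.2 ± 3.96 against 3424 ± 662) and Oog4 (46.3 ± 3.93 against 2866 ± 778). Of the genome activation and 2-cell burst list, 28 of 34 rose, 3 fell and 3 did not pass (camera higher, adjusted p = 0.0094, and adjusted p = 0.45 with an estimated correlation). Members included Obox6 (a homeobox gene, 924 ± 15.2 against 3.14 ± 1.72) and Zfp54 (141 ± 8.55 against 1.99 ± 0.856). Maternal oocyte transcripts went the other way: 29 of 40 fell, 2 rose and 9 did not pass (camera lower, adjusted p = 6.9e-20). Examples were H1foo (the oocyte linker histone, 112 ± 10.2 against 3996 ± 221) and Rfpl4 (234 ± 18.5 against 6926 ± 1304). The maternal list was the only one of this comparison whose camera call held with an estimated correlation. Cytosolic ribosomal proteins moved together, and 49 of 50 rose and 1 fell (camera higher, adjusted p = 4.8e-16, and adjusted p = 0.30 with an estimated correlation). Among them were Rps3 (230.1 ± 25.9 against 1.38 ± 0.434) and Rpsa (72.2 ± 5.03 against 0.354 ± 0.193). In ribosome biogenesis, 29 of 30 rose and 1 did not pass (camera higher, adjusted p = 1.3e-08, and adjusted p = 0.089 with an estimated correlation). These included Nop2 (a nucleolar RNA methyltransferase, 158 ± 35.2 against 0.546 ± 0.224). Of nucleotide synthesis genes, 18 of 23 rose, 2 fell and 3 did not pass (camera higher, adjusted p = 0.0030, and adjusted p = 0.44 with an estimated correlation). A member was Ppat (the first committed step of purine synthesis, 639 ± 42.5 against 2.19 ± 1.18). MYC targets outside the nucleolus gave 24 up, 2 down and 3 not passed of 29 (camera higher, adjusted p = 3.2e-04, and adjusted p = 0.14 with an estimated correlation). An example was Tfrc (the transferrin receptor, 583 ± 47.6 against 5.1 ± 0.316). In pyruvate handling, Ldha (lactate dehydrogenase A, 65 ± 6.47 against 2.89 ± 0.278) and Mpc2 (a subunit of the mitochondrial pyruvate carrier, 145 ± 18.1 against 2.48 ± 0.176) rose. Markers of other cell types did not move as lists. Of cumulus and granulosa markers, 4 of 7 rose, 1 fell and 2 did not pass (camera higher, adjusted p = 0.90). Of sperm and blood markers, 3 of 4 rose and 1 fell (camera higher, adjusted p = 0.90). In all, 14402 of 20160 genes passed the threshold, 11634 higher and 2768 lower. Higher genes were 80.8% of these, and 51.6%, 47.5% and 45.8% under the 3 scalings. All genes had 0.85 as their median log2 change, and 0.06, -0.01 and -0.19 under them.

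Early 8-cell embryos (66 h) were set against late 2-cell embryos to describe the end of the 2-cell programme. The largest rises included Vnn1 (a pantetheinase, 260.3 ± 27.6 against 0.283 ± 0.106), Fbp2 (a fructose bisphosphatase, 150.5 ± 14.2 against 1.2 ± 0.274), Cldn4 (a tight junction protein, 131 ± 16 against 1.14 ± 0.409) and Slc6a8 (the creatine transporter, 169 ± 12 against 2.33 ± 0.761). Vnn1 lies on chromosome 10, 23894688 to 23905343. The largest falls included Tcl1b1 (1.47 ± 1.08 against 2075 ± 512), Wee2 (an oocyte cell cycle kinase, 0.292 ± 0.505 against 743 ± 91.2) and Accsl (0.809 ± 0.583 against 1003 ± 177). Maternal oocyte transcripts fell as a list, and all 40 fell (camera lower, adjusted p = 1.1e-14). Among them were Btg4 (an adaptor for removal of maternal mRNA, 6.08 ± 0.638 against 1749 ± 139) and Tcl1 (10.3 ± 1.61 against 4054 ± 563). Btg4 lies on chromosome 9, 51060901 to 51119875. The 2-cell burst list fell too, and 32 of 34 fell, 1 rose and 1 did not pass (camera lower, adjusted p = 2.7e-10). Nuclear-encoded respiratory genes continued upward: 54 of 66 rose, 3 fell and 9 did not pass, against 54 up and 4 down adjusted over the list alone (camera higher, adjusted p = 2.0e-18, and adjusted p = 0.10 with an estimated correlation). These included Ndufa8 (69.6 ± 2.44 against 2.72 ± 0.325) and Ndufs6 (50.9 ± 3.13 against 1.76 ± 0.237). Ribosomal protein genes gave all 50 up (camera higher, adjusted p = 3.6e-21, and adjusted p = 0.12 with an estimated correlation). Trophectoderm markers gave 10 up, 5 down and 7 not passed of 22 (camera higher, adjusted p = 0.011, and adjusted p = 0.17 with an estimated correlation). Members included Aqp3 (a glycerol and water channel, 103 ± 37.5 against 1.37 ± 0.11) and Tead4 (a transcription factor that trophectoderm needs, 277 ± 35.9 against 27.7 ± 2.37). Lactate dehydrogenase B fell, Ldhb (5.44 ± 0.462 against 279.8 ± 13.6). The pyruvate carrier subunit rose, Mpc2 (619 ± 4.62 against 145 ± 18.1). Here 14597 of 20160 genes passed the threshold, 4942 higher and 9655 lower. Higher genes were 33.9% of these, and 35.8%, 51.1% and 49.5% under the 3 scalings. All genes had -0.46 as their median log2 change, and -0.33, 0.03 and -0.0045 under them.

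Blastocysts (114 h) were compared with early 8-cell embryos to describe the formation of the first lineages. The largest rises included Adh1 (alcohol dehydrogenase, 8095 ± 1176 against listed at 0), Id2 (an inhibitor of DNA binding factors, 3632 ± 992 against 0.195 ± 0.337), Fabp3 (a fatty acid binding protein, 13405 ± 3129 against 15.6 ± 4.5) and Lgals1 (galectin, 4156 ± 749 against 0.548 ± 0.368). Adh1, at 0 apart from the offset in early 8-cell embryos, lies on chromosome 3, 138260991 to 138290698, and Id2 on chromosome 12, 25093799 to 25097140. Among the largest falls were Map7d2 (0.361 ± 0.167 against 1360.3 ± 130.2), Acsl4 (an acyl-CoA synthetase, 0.893 ± 0.28 against 722 ± 83.8), Cux2 (0.411 ± 0.348 against 278 ± 15.4) and Sox15 (9.35 ± 3.86 against 1513 ± 183). Trophectoderm markers rose most: 18 of 22 rose, 3 fell and 1 did not pass (camera higher, adjusted p = 1.3e-12). An example was Tspan8 (2856 ± 400.3 against 5.78 ± 1.5). In the primitive endoderm list, 14 of 17 rose, 2 fell and 1 did not pass (camera higher, adjusted p = 4.0e-08). Among them was Sparc (a matrix protein, 164 ± 27.7 against 0.774 ± 0.884). Nuclear-encoded respiratory genes gave 61 up, 1 down and 4 not passed of 66 (camera higher, adjusted p = 7.5e-27). In glycolysis, 11 of 21 rose, 5 fell and 5 did not pass (camera higher, adjusted p = 5.8e-04, and adjusted p = 0.091 with an estimated correlation). These included Tpi1 (376 ± 65.9 against 4.13 ± 0.957), Gapdh (157 ± 30.4 against 1.45 ± 0.763) and Aldoa (1057 ± 75.9 against 94.8 ± 6.48). Fatty acid oxidation genes gave 12 up, 4 down and 1 not passed of 17 (camera higher, adjusted p = 5.6e-05, and adjusted p = 0.13 with an estimated correlation). A member was Acaa2 (409 ± 66.6 against 9.39 ± 2.88). Ribosome biogenesis fell: 28 of 30 fell, 1 rose and 1 did not pass (camera lower, adjusted p = 1.4e-09). Examples were Nolc1 (28.3 ± 7.71 against 483 ± 25.7) and Ddx21 (13.2 ± 4.12 against 212 ± 20.2). The pyruvate carrier subunit fell to a low level, Mpc2 (32.6 ± 2.54 against 619 ± 4.62). Between these stages 12321 of 20160 genes passed the threshold, 3451 higher and 8870 lower. Higher genes were 28% of these, and 55.7%, 48.1% and 56.4% under the 3 scalings. All genes had -0.36 as their median log2 change, and 0.02, -0.02 and 0.20 under them.

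Between neighbouring ages of the standard course, the number of genes past the threshold was early 2-cell to mid 2-cell 10214, mid 2-cell to late 2-cell 11907, late 2-cell to very late 2-cell 6851 and very late 2-cell to early 4-cell 8842. Then it was early 4-cell to late 4-cell 8067, late 4-cell to early 8-cell 1501, early 8-cell to late 8-cell 1438 and late 8-cell to morula 509. For the last steps it was morula to early 16-cell 7574, early 16-cell to early 32-cell 4175 and early 32-cell to blastocyst 8418. The step from 78 to 80 h may also reflect a split of libraries into 2 kinds, weighed below. Late 8-cell embryos had only 2 libraries, and the counts of their steps fell without the second. The counts of several steps depended on the other groups in the fit. With only the groups compared, 219 genes passed from late 4-cell to early 8-cell, 163 from early to late 8-cell, 3 from late 8-cell to morula and 7242 from early 16-cell to early 32-cell.

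The position of each library on the line from early 2-cell (0) to late 4-cell (1) embryos was used to ask whether embryos without pyruvate lag behind those of the same age. At 42 h, embryos without pyruvate lay at 0.0558 ± 0.0066 (SD, n = 4) against 0.259 ± 0.0257 (SD, n = 4), a difference of -0.203 (exact p = 0.029, adjusted p = 0.036). At 48 h they lay at 0.272 ± 0.0438 (SD, n = 5) against 0.617 ± 0.0018 (SD, n = 3), a difference of -0.344 (exact p = 0.018, adjusted p = 0.036). At 52 h they lay at 0.419 ± 0.0059 (SD, n = 4) against 0.775 ± 0.0045 (SD, n = 3), a difference of -0.356 (exact p = 0.029, adjusted p = 0.036). At 55 h, when standard embryos had 4 cells, 2-cell embryos without pyruvate lay at 0.735 ± 0.0382 (SD, n = 4) against 0.916 ± 0.0099 (SD, n = 4), a difference of -0.181 (exact p = 0.029, adjusted p = 0.036). Every library without pyruvate lay below every standard library of its age, and the p-values at 42, 48, 52 and 55 h were the smallest that these group sizes allow.

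**Figure D2:**
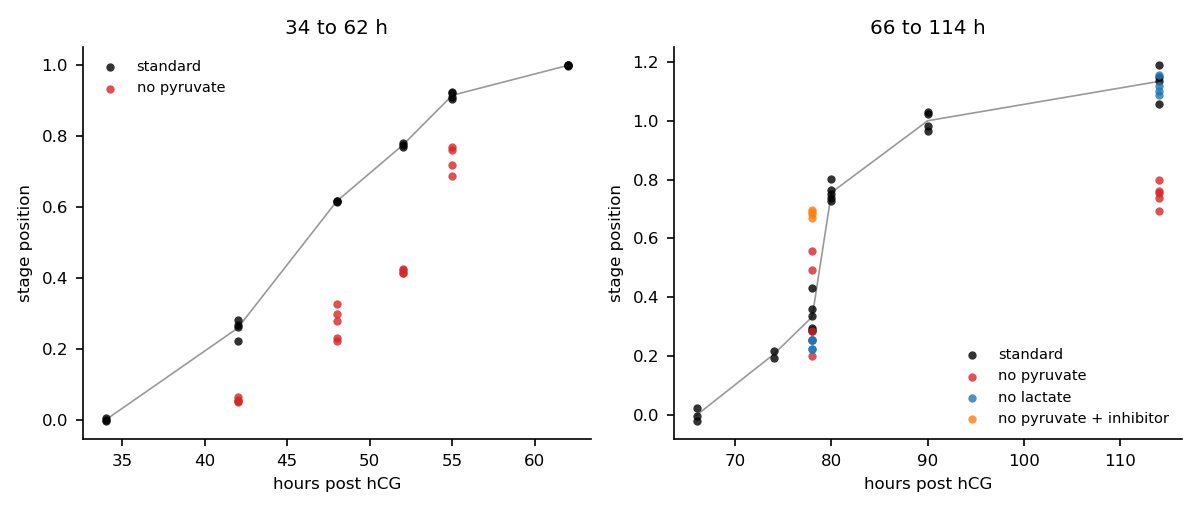
Stage position (vertical axis, 0 and 1 at the end groups of each line) against hours after hCG (horizontal axis), a point per library, coloured by medium, for 2-cell and 4-cell libraries (left) and morulae and blastocysts (right). At 52 h the mean was 0.419 without pyruvate and 0.775 in standard medium.

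At 42 h, 2-cell embryos without pyruvate kept more maternal RNA and had less of the RNA that standard embryos were gaining. Maternal oocyte transcripts gave 17 up, 1 down and 23 not passed of 41 (camera higher, adjusted p = 1.2e-10). These included Ooep (a subcortical maternal complex protein, 471 ± 142 against 97.8 ± 62.9). Rises were large for Rgs2 (1394 ± 329.9 against 157 ± 122) and Fbxw28 (5553 ± 1444 against 718 ± 299.6). The genome activation list gave 22 down, 2 up and 10 not passed of 34, against 2 up and 23 down adjusted over the list alone (camera lower, adjusted p = 6.2e-04, and adjusted p = 0.43 with an estimated correlation). Examples were Obox6 (28 ± 1.99 against 244 ± 40.1) and Obox3 (80.9 ± 12.9 against 541 ± 69.9). Among the largest falls were Cdk2ap1 (3.68 ± 0.894 against 132 ± 22.2), Alppl2 (9.26 ± 7.67 against 231 ± 43.2) and Selenos (5.35 ± 1.25 against 161 ± 41.7). Ribosomal protein genes gave 45 down, 1 up and 4 not passed of 50, against 1 up and 46 down adjusted over the list alone (camera lower, adjusted p = 1.3e-15, and adjusted p = 0.30 with an estimated correlation). Ribosome biogenesis genes gave 26 down, 3 up and 1 not passed of 30 (camera lower, adjusted p = 1.2e-09, and adjusted p = 0.28 with an estimated correlation). A member was Nop2 (1.43 ± 0.704 against 31.1 ± 5.12). Of the 12 pyruvate, lactate, glucose and MYC family genes fixed for all media comparisons, 1 rose, 8 fell and 3 did not pass. Lactate dehydrogenase A and the lactate and pyruvate transporter Slc16a1 fell, Ldha (12.1 ± 2.13 against 76.8 ± 12.2) and Slc16a1 (13 ± 2.93 against 68.5 ± 13.7). Mpc2 (8.5 ± 1.0 against 44.9 ± 7.97) and Pdk1 (an inhibitory kinase of pyruvate dehydrogenase, 9.54 ± 2.06 against 23.1 ± 2.71) fell as well, while Ldhb (3974 ± 402 against 1240.0 ± 353) rose. Ldha lies on chromosome 7, 46841475 to 46855627 and Mpc2 on chromosome 1, 165460637 to 165481214. At this age 7624 of 20739 genes passed the threshold, 1157 higher and 6467 lower. Higher genes were 15.2% of these, and 44.3%, 51.4% and 39.7% under the 3 scalings. All genes had -0.26 as their median log2 change, and 7.5e-05, 0.07 and 0.09 under them.

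At 48 h the maternal list stood further above standard medium: 32 of 41 rose, 2 fell and 7 did not pass, against 33 up and 2 down adjusted over the list alone (camera higher, adjusted p = 2.4e-13). Examples were Btg4 (9569.9 ± 983 against 1749 ± 139) and Rfpl4 (3211 ± 678 against 234 ± 18.5). By now the genome activation list was higher without pyruvate, as 16 of 34 rose, 7 fell and 11 did not pass (camera higher, adjusted p = 0.022, and adjusted p = 0.78 with an estimated correlation). Its members differed, with Zscan4f (1104 ± 231 against 249 ± 25.3) higher and Obox6 (283 ± 74.5 against 924 ± 15.2) lower. Zscan4f lies on chromosome 7, 11397915 to 11402318, in a cluster of near-identical copies that makes its level uncertain. Ribosome biogenesis gave 29 down and 1 not passed of 30 (camera lower, adjusted p = 1.3e-13, and adjusted p = 0.11 with an estimated correlation). Serine and one-carbon genes gave 7 down, 2 up and 2 not passed of 11 (camera lower, adjusted p = 0.12). Among them was Phgdh (the first enzyme of serine synthesis, 5.78 ± 0.819 against 44.2 ± 5.72). The largest rises included Psenen (162 ± 36.8 against 9.6 ± 2.9) and Nlrp4f (2276 ± 557 against 182 ± 6.27). Falls were led by Riox2 (11.2 ± 6.19 against 189 ± 25.9) and Usp22 (8.9 ± 4.3 against 153 ± 23). Among the fixed pyruvate, lactate, glucose and MYC genes, 2 rose, 6 fell and 4 did not pass. Myc (a transcription factor of growth, 1.23 ± 0.442 against 9.58 ± 1.93) fell, and Ldhb (1709 ± 289.6 against 279.8 ± 13.6) and Slc2a1 (35.1 ± 6.96 against 7.18 ± 0.635) rose. Myc lies on chromosome 15, 61985391 to 61990374. At this age 11783 of 20739 genes passed the threshold, 4677 higher and 7106 lower. Higher genes were 39.7% of these, and 51.8%, 49.1% and 48.9% under the 3 scalings. All genes had -0.14 as their median log2 change, and 0.07, 0.01 and 0.05 under them.

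At 52 h the 2-cell burst list was well above the standard embryos, which had by then passed it: 23 of 34 rose, 3 fell and 8 did not pass (camera higher, adjusted p = 1.6e-06, and adjusted p = 0.20 with an estimated correlation). These included Zscan4f (920.2 ± 158 against 68.3 ± 15). Maternal transcripts gave 35 up, 3 down and 3 not passed of 41 (camera higher, adjusted p = 1.1e-11). Members included Btg4 (2688 ± 182 against 259.8 ± 22) and Nobox (219 ± 14 against 14.6 ± 3.36). Nuclear-encoded respiratory genes were lower: 47 of 66 fell, 5 rose and 14 did not pass (camera lower, adjusted p = 5.1e-07, and adjusted p = 0.39 with an estimated correlation). Examples were Uqcrc1 (21.1 ± 4.25 against 146 ± 9.58) and Uqcrfs1 (39.9 ± 10.2 against 183 ± 23.1). In mitosis, 18 of 24 fell, 3 rose and 3 did not pass (camera lower, adjusted p = 3.3e-04, and adjusted p = 0.20 with an estimated correlation). Among them were Cdc20 (85.2 ± 14.6 against 863 ± 109) and Aurka (131 ± 17.8 against 821 ± 106), which act in spindle assembly and exit from mitosis. Large rises included Nlrp9a (701 ± 236 against 35 ± 5.93) and H2-Aa (82.9 ± 4.34 against 3.74 ± 1.49). Large falls included Isyna1 (which makes inositol phosphate, 8.14 ± 2.99 against 199 ± 26.5) and Mrpl19 (1.42 ± 0.932 against 41.6 ± 4.04). Of the fixed genes, 3 rose, 4 fell and 5 did not pass. Myc (2.87 ± 1.91 against 34.5 ± 2.01) fell by the most of these, and Pdha1 (a pyruvate dehydrogenase subunit, 31.7 ± 5.56 against 126 ± 7.4) fell. Ldhb (770.0 ± 143 against 134 ± 16.5) and Slc2a1 (13.1 ± 3.66 against 3.05 ± 0.546) rose. Here 13119 of 20739 genes passed the threshold, 6618 higher and 6501 lower.

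At 55 h the comparison of 2-cell embryos without pyruvate and standard early 4-cell embryos matched age but not cell number. Burst genes were still present without pyruvate: 31 of 34 rose and 3 did not pass (camera higher, adjusted p = 1.5e-15). These included Duxf3 (the factor that drives the 2-cell burst, 72.9 ± 45.3 against 0.26 ± 0.367) and Pramef25 (202 ± 90.5 against 0.55 ± 0.39), both multi-copy genes of uncertain level. Maternal transcripts gave 37 up and 4 not passed of 41 (camera higher, adjusted p = 4.2e-10). Among them were Omt2a (7911 ± 1233 against 980.0 ± 167) and Oosp1 (346 ± 78.6 against 20.9 ± 6.0). The pyruvate dehydrogenase and TCA cycle list was lower, and 13 of 25 fell, 3 rose and 9 did not pass (camera lower, adjusted p = 6.0e-04). These included Pdhx (19.7 ± 5.77 against 77 ± 5.21) and Sucla2 (43.3 ± 3.33 against 106 ± 9.28). Mitochondrially encoded mRNAs gave 11 up and 2 not passed of 13, against 12 up and 0 down adjusted over the list alone (camera higher, adjusted p = 1.6e-04, and adjusted p = 0.32 with an estimated correlation). A member was mt-Co3 (2560.2 ± 490.3 against 582 ± 111). Atf3 (17 ± 15.4 against 0.0093 ± 0.0185), Pmaip1 (a p53 target that promotes cell death, 69.3 ± 19.7 against 6.79 ± 1.67), Btg2 (60.1 ± 23.6 against 4.92 ± 2.61) and Stard4 (a cholesterol transport protein, 65.2 ± 48.8 against 1.78 ± 1.58) were higher. The largest falls included Vnn1 (0.453 ± 0.492 against 31.4 ± 11.4), Galk1 (galactokinase, 2.11 ± 1.56 against 36.6 ± 3.38) and Alad (of heme synthesis, 6.41 ± 4.03 against 72.6 ± 17.2). Among the fixed genes 6 rose, 4 fell and 2 did not pass. Ldha (48.9 ± 26.4 against 17.8 ± 7.24) and Slc2a3 (a glucose transporter, 118 ± 29.4 against 31.5 ± 19.7) were higher. Myc (19.6 ± 7.73 against 54.8 ± 12.2) and Mpc2 (195 ± 21.4 against 389 ± 91) were lower. Slc2a3 lies on chromosome 6, 122727809 to 122801640. In this comparison 11855 of 20739 genes passed the threshold, 7816 higher and 4039 lower. Higher genes were 65.9% of these, and 56.8%, 47.3% and 46.2% under the 3 scalings. All genes had 0.27 as their median log2 change, and 0.13, -0.02 and -0.07 under them.

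The change from 42 to 52 h was compared between the media to test which genes moved differently, and values are log2 differences of the 2 changes. Genome activation genes had a more upward change without pyruvate: 30 of 34 were higher and 4 did not pass (camera higher, adjusted p = 5.5e-13, and adjusted p = 0.14 with an estimated correlation). Examples were Zfp54 (4.55), Obox3 (3.25) and Ddit4l (4.39). Maternal transcripts had one too, as 27 of 41 were higher, 3 were lower and 11 did not pass (camera higher, adjusted p = 6.8e-04, and adjusted p = 0.24 with an estimated correlation). Among them were Btg4 (3.05) and Tcl1 (3.38). Mitosis genes gave 10 down, 3 up and 11 not passed of 24 (camera lower, adjusted p = 5.1e-05, and adjusted p = 0.24 with an estimated correlation). These included Cdc20 (-2.76) and Aurka (-2.09). In pyruvate, lactate and shuttle handling, 15 of 26 were higher, 1 was lower and 10 did not pass (camera higher, adjusted p = 0.043, and adjusted p = 0.34 with an estimated correlation). Members included Ldha (3.48), Slc16a1 (2.71) and Pdk3 (2.78). The largest differences were Rfpl4b (6.02), Cldn6 (4.97) and Klf10 (4.86) upward and Bub3 (of the spindle checkpoint, -3.63) and Pfn1 (profilin, -3.61) downward. Myc differed by -2.45. For this interaction 10294 of 20739 genes passed the threshold, 7354 higher and 2940 lower. Higher genes were 71.4% of these, and 57.8%, 50.2% and 53% under the 3 scalings. All genes had 0.45 as their median log2 change, and 0.18, -0.02 and 0.08 under them.

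Morulae at 78 h were compared between media to ask what the absence of pyruvate changes at this later stage. Among the largest rises were Cd81 (a tetraspanin, 119 ± 31.2 against 1.16 ± 0.569), Glrx (glutaredoxin, 66.3 ± 15.7 against 1.0 ± 0.676), Slc40a1 (the iron exporter ferroportin, 42.6 ± 20.4 against 0.754 ± 0.707), Apoe (a lipid carrier, 286 ± 44.1 against 14.1 ± 5.28) and Hmox1 (heme oxygenase, 48.4 ± 32.7 against 1.38 ± 0.928). Cd81 lies on chromosome 7, 143052739 to 143067934, Glrx on chromosome 13, 75839868 to 75850154 and Slc40a1 on chromosome 1, 45908068 to 45926523. Glycolysis genes rose as a list: 16 of 21 rose, 1 fell and 4 did not pass (camera higher, adjusted p = 2.4e-04, and adjusted p = 0.30 with an estimated correlation). Examples were Ldha (84.6 ± 11.5 against 11.3 ± 3.91), Pkm (pyruvate kinase, 118 ± 63 against 14.9 ± 4.79) and Gpi1 (94.5 ± 27.4 against 23.1 ± 6.09). The glucose transporters rose, Slc2a3 (618 ± 374 against 114 ± 73.6) and Slc2a1 (24.3 ± 18.4 against 4.88 ± 3.54). Oxidative stress and NRF2 targets gave 14 up and 6 not passed of 20, against 17 up and 0 down adjusted over the list alone (camera higher, adjusted p = 3.0e-05, and adjusted p = 0.17 with an estimated correlation). Among them were Prdx1 (a peroxiredoxin, 1762 ± 253 against 451 ± 79.7) and Gclm (of glutathione synthesis, 103 ± 18.4 against 35.2 ± 7.58). In the p53 list, 14 of 17 rose and 3 did not pass (camera higher, adjusted p = 0.0013, and adjusted p = 0.41 with an estimated correlation). These included Cdkn1a (an inhibitor of cyclin-dependent kinases, 402 ± 92.6 against 147 ± 21.5), Btg2 (51 ± 44.4 against 5.26 ± 0.944) and Trp53inp1 (83.3 ± 39.9 against 20.6 ± 5.77). Cdkn1a lies on chromosome 17, 29090976 to 29100727. Hypoxia targets gave 10 up and 7 not passed of 17, against 11 up and 0 down adjusted over the list alone (camera higher, adjusted p = 0.047, and adjusted p = 0.38 with an estimated correlation). Among them was Ero1l (121 ± 25.4 against 13.7 ± 4.68). Integrated stress targets gave 16 up, 1 down and 7 not passed of 24, against 17 up and 2 down adjusted over the list alone (camera higher, adjusted p = 0.013, and adjusted p = 0.30 with an estimated correlation). An example was Slc7a3 (an arginine and lysine transporter, 7.57 ± 2.56 against 0.261 ± 0.244). Cholesterol synthesis gave 10 up and 11 not passed of 21 (camera higher, adjusted p = 0.14). A member was Srebf2 (90.6 ± 20.6 against 30.2 ± 8.95). Pentose phosphate genes gave 3 up and 4 not passed of 7, against 4 up and 0 down adjusted over the list alone (camera higher, adjusted p = 0.73). Burst genes remained above standard morulae at low levels, and 25 of 33 rose and 8 did not pass, against 26 up and 1 down adjusted over the list alone (camera higher, adjusted p = 3.0e-04, and adjusted p = 0.41 with an estimated correlation). An example was Zscan4d (12.2 ± 8.63 against 0.367 ± 0.282), which lies on chromosome 7, 11161374 to 11166159 in the same multi-copy cluster. Mitochondrially encoded mRNAs fell: all 13 fell (camera lower, adjusted p = 4.5e-10, and adjusted p = 0.30 with an estimated correlation). An example was mt-Nd2 (770.2 ± 682 against 3597 ± 3023). The mitochondrial share of a library was 1.37% to 8.27% in standard morulae and 0.235% to 2.09% without pyruvate. Ribosome biogenesis gave 12 down, 1 up and 17 not passed of 30, against 2 up and 13 down adjusted over the list alone (camera lower, adjusted p = 1.3e-08). Among them was Polr1b (53.6 ± 18.2 against 115 ± 19.7). Of pluripotency genes, 8 of 19 fell, 3 rose and 8 did not pass, against 4 up and 8 down adjusted over the list alone (camera lower, adjusted p = 0.0035). Esrrb (14.8 ± 3.34 against 39 ± 14.2) was lower. The largest falls included Hmga2 (a chromatin protein, 35.1 ± 10.6 against 143 ± 74.8), Twnk (the mitochondrial DNA helicase, 33.6 ± 7.48 against 159 ± 179) and Hcrt (6.48 ± 3.37 against 35.9 ± 9.32). Hmga2 lies on chromosome 10, 120361275 to 120476469. The log2 change of Twnk was -1.72, and -1.08 without standard libraries 1 and 2. Myc, at 36.6 ± 11.1 without pyruvate and 46.3 ± 22.9 in standard medium, did not pass, and passed only when standard libraries 1 and 2 were left out. Of the fixed genes, 6 rose, 1 fell and 5 did not pass. In these morulae 6320 of 16032 genes passed the threshold, 5257 higher and 1063 lower. Higher genes were 83.2% of these, and 64.5%, 47.8% and 49.7% under the 3 scalings. All genes had 0.28 as their median log2 change, and 0.08, -0.07 and -0.03 under them.

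**Figure D3:**
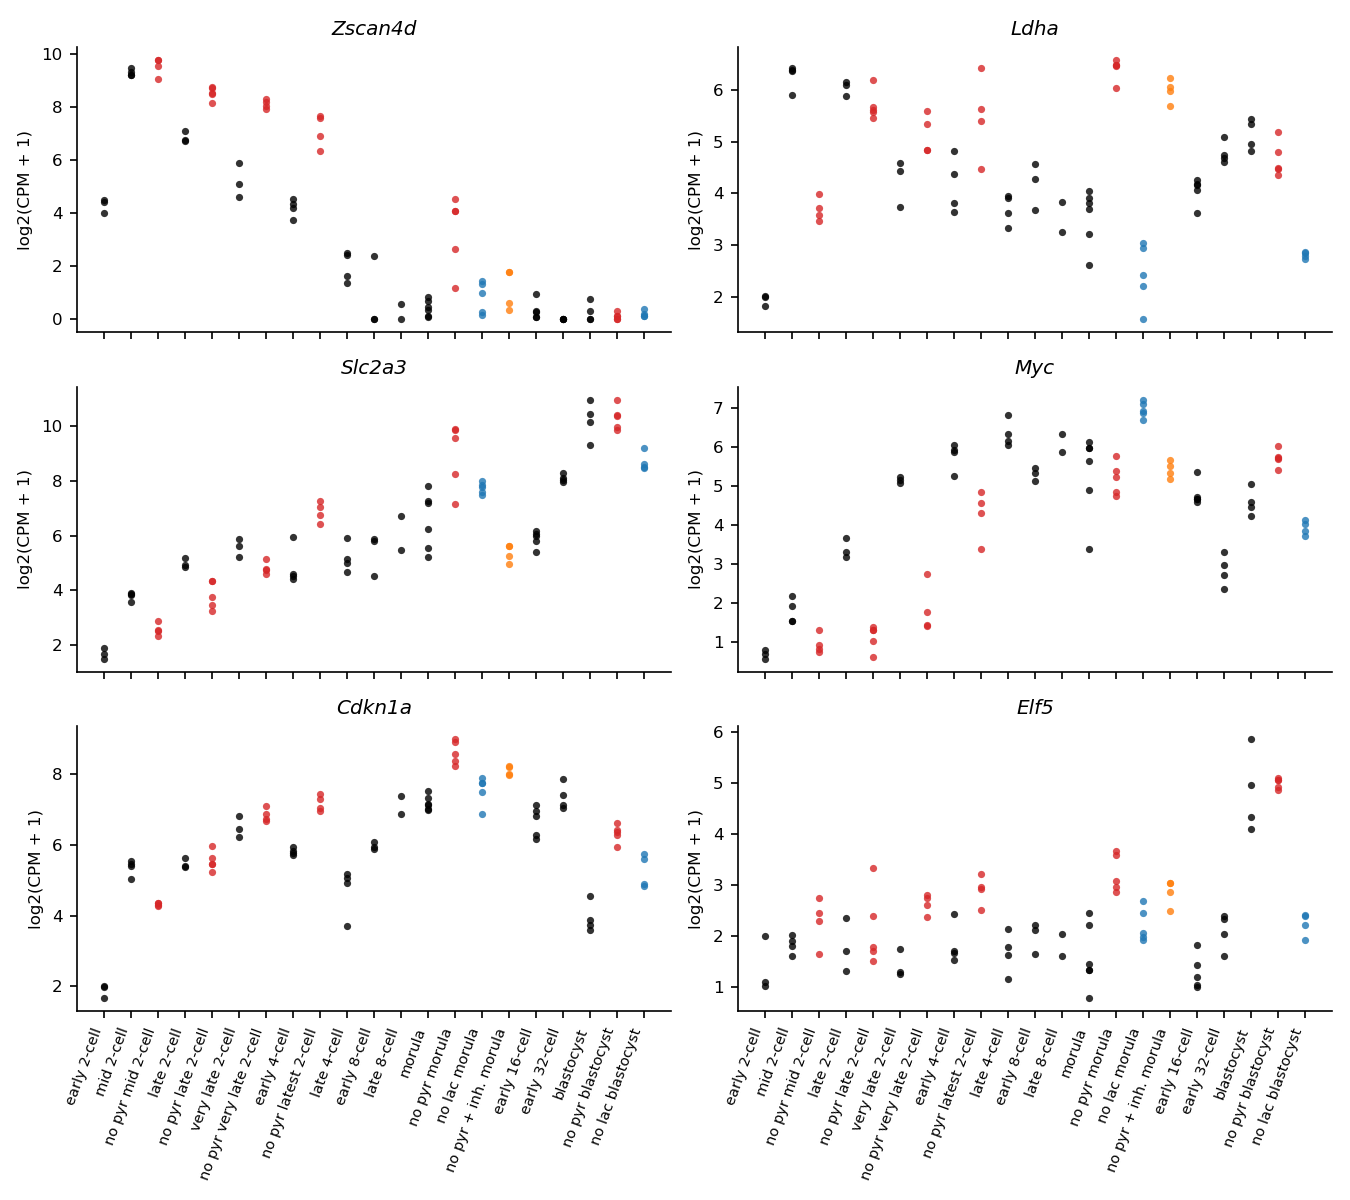
Level of Zscan4d, Ldha, Slc2a3, Myc, Cdkn1a and Elf5 as log2(CPM + 1) (vertical axis) in each library, by group (horizontal axis). In morulae without pyruvate the mean of Ldha was 84.6 CPM against 11.3 CPM in standard morulae.

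Morulae without lactate were compared with standard morulae to ask what the absence of lactate changes, and 1891 of 16032 genes passed the threshold, 1343 higher and 548 lower. Higher genes were 71% of these, and 59.7%, 48.2% and 49.4% under the 3 scalings. All genes had 0.10 as their median log2 change, and 0.04, -0.02 and -0.01 under them. The largest rises included Sf3a2 (a splicing factor, 26.8 ± 6.92 against 3.48 ± 1.94), Rab27a (of vesicle transport, 58.2 ± 5.16 against 9.76 ± 2.86), Sidt2 (641 ± 189 against 122 ± 33.5) and Mixl1 (a homeobox factor, 52.1 ± 12.4 against 10.3 ± 4.94). Falls were led by Phlda2 (an imprinted growth regulator, 4.15 ± 1.94 against 25.8 ± 17.7), Pigp (118 ± 19.4 against 416 ± 268) and Myl12b (36.4 ± 5.18 against 99.7 ± 28.6). Ribosomal protein genes gave 20 down and 30 not passed of 50 (camera lower, adjusted p = 1.1e-16, and adjusted p = 0.71 with an estimated correlation). These included Rpl37 (44.6 ± 4.74 against 98 ± 13.2). Of nuclear-encoded respiratory genes, 8 of 66 fell and 58 did not pass, against 0 up and 9 down adjusted over the list alone (camera lower, adjusted p = 4.9e-07, and adjusted p = 0.71 with an estimated correlation). A member was Ndufb10 (65.3 ± 9.44 against 113 ± 20.3). Of mitochondrially encoded mRNAs, 4 of 13 rose and 9 did not pass, against 7 up and 0 down adjusted over the list alone (camera higher, adjusted p = 0.024, and adjusted p = 0.97 with an estimated correlation). Their share was 6.93 ± 1.05% (SD, n = 5) against 3.58 ± 2.52% (SD, n = 6). Myc (123 ± 17.8 against 46.3 ± 22.9) and Hk2 (hexokinase, 94.9 ± 13.8 against 37.7 ± 17.7) rose. Ldha (4.77 ± 2.19 against 11.3 ± 3.91) and Pou5f1 (the pluripotency factor OCT4, 111 ± 17.9 against 212 ± 37.8) fell. Of the 12 fixed genes, 10 did not pass. On the line from early 8-cell (0) to early 32-cell (1) embryos, these morulae lay at 0.243 ± 0.0168 (SD, n = 5) against 0.334 ± 0.0568 (SD, n = 6), a difference of -0.091 (exact p = 0.0065, adjusted p = 0.026). Without standard morula libraries 1 and 2, the count of genes was 3102.

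Morulae without pyruvate were set against morulae without lactate to separate the nutrients, and 6795 of 16032 genes passed the threshold, 4713 higher and 2082 lower. Higher genes were 69.4% of these, and 58%, 50.1% and 51.2% under the 3 scalings. All genes had 0.19 as their median log2 change, and 0.05, -0.03 and -0.01 under them. Cd81 (119 ± 31.2 against 0.746 ± 0.285), Ldha (84.6 ± 11.5 against 4.77 ± 2.19) and Glrx (66.3 ± 15.7 against 2.06 ± 1.09) were higher without pyruvate. Hmga2 (35.1 ± 10.6 against 365 ± 46.6), Myc (36.6 ± 11.1 against 123 ± 17.8) and mt-Cytb (mitochondrial cytochrome b, 4222 ± 3509 against 41086 ± 7367) were lower. Glycolysis genes gave 15 up, 2 down and 4 not passed of 21 (camera higher, adjusted p = 6.9e-04, and adjusted p = 0.36 with an estimated correlation). Mitochondrially encoded mRNAs gave all 13 down (camera lower, adjusted p = 3.3e-10, and adjusted p = 0.36 with an estimated correlation). On the stage line, morulae without pyruvate and standard morulae lay at 0.359 ± 0.157 (SD, n = 5) against 0.334 ± 0.0568 (SD, n = 6), a difference of 0.0248 (exact p = 0.72, adjusted p = 0.72).

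Morulae without pyruvate were compared with and without KY-PYR-9 to ask which transcripts change with the compound. Most changed genes were lower with it: 12139 of 16032 genes passed the threshold, 1380 higher and 10759 lower. Higher genes were 11.4% of these, and 44.6%, 48.5% and 47.9% under the 3 scalings. All genes had -0.90 as their median log2 change, and -0.18, -0.11 and -0.05 under them. The steepest falls included Glrx (1.72 ± 0.685 against 66.3 ± 15.7), Slc40a1 (1.27 ± 0.77 against 42.6 ± 20.4), Pmaip1 (8.1 ± 2.44 against 200.5 ± 154) and Anxa2 (an annexin, 16.4 ± 0.994 against 277 ± 74.1). Slc2a3 (40.7 ± 8.92 against 618 ± 374) and Krt18 (a keratin of trophectoderm, 30.9 ± 6.37 against 349 ± 238) fell as well. Among the largest rises were mt-Atp8 (2948 ± 955 against 116 ± 97) and Trim43c (593 ± 98.9 against 29.3 ± 10.9). Prps1 (8218 ± 1025 against 1655 ± 215) and Spic (2070.0 ± 187 against 286 ± 51.7) rose too. Mitochondrially encoded mRNAs gave all 13 up (camera higher, adjusted p = 4.5e-17, and adjusted p = 0.22 with an estimated correlation). Ribosomal protein genes gave 38 up, 1 down and 11 not passed of 50 (camera higher, adjusted p = 1.7e-31, and adjusted p = 0.22 with an estimated correlation). Among them was Rps2 (188 ± 23.2 against 41.1 ± 4.55). In ribosome biogenesis, 13 of 30 fell, 6 rose and 11 did not pass, against 6 up and 12 down adjusted over the list alone, but the majority turned under median-ratio scaling (20 up, 0 down), under quantile scaling (12 up, 2 down) and with the length trend removed (18 up, 0 down) (camera higher, adjusted p = 0.050, and adjusted p = 0.72 with an estimated correlation, though its median log2 change was -0.34 and its mean -0.21). Among MYC targets outside the nucleolus, 17 of 29 fell, 8 rose and 4 did not pass, but the majority turned under median-ratio scaling (14 up, 3 down) and with the length trend removed (12 up, 4 down) (camera higher, adjusted p = 0.13, though its median log2 change was -0.57 and its mean -0.31). Cdk4 (93.6 ± 5.7 against 241 ± 19.9) was lower and Apex1 (433 ± 39.3 against 150.5 ± 21.9) higher. Glycolysis genes gave 19 down and 2 not passed of 21 (camera lower, adjusted p = 0.22). These included Gpi1 (15.5 ± 1.42 against 94.5 ± 27.4). Pou5f1 (36.7 ± 11.2 against 148 ± 37.3) fell. None of the fixed genes rose, 6 fell and 6 did not pass. Among the last was Ldha, at 63 ± 9.78 with the inhibitor against 84.6 ± 11.5 without, which passed when only the groups compared were fitted. On the stage line these morulae lay at 0.684 ± 0.0119 (SD, n = 4) against 0.359 ± 0.157 (SD, n = 5), a difference of 0.325 (exact p = 0.016, adjusted p = 0.036).

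Against standard morulae, in those without pyruvate and with KY-PYR-9, 9518 of 16032 genes passed the threshold, 1959 higher and 7559 lower. Higher genes were 20.6% of these, and 55.9%, 47.9% and 51.5% under the 3 scalings. All genes had -0.51 as their median log2 change. Cdk2ap1 (1752 ± 232 against 159.7 ± 21.3), Ldha (63 ± 9.78 against 11.3 ± 3.91) and Srebf2 (the master regulator of sterol synthesis, 193 ± 31.6 against 30.2 ± 8.95) were higher. Mcm2 (of the replicative helicase, 24.3 ± 3.18 against 678 ± 975), Twnk (4.76 ± 0.977 against 159 ± 179), Bag1 (17.2 ± 5.91 against 244 ± 41.4), Cad (20.5 ± 0.471 against 94 ± 17.7), Gata6 (25.2 ± 2.73 against 129.5 ± 57) and Pou5f1 (36.7 ± 11.2 against 212 ± 37.8) were lower. DNA replication genes gave 20 down and 5 not passed of 25 (camera lower, adjusted p = 0.0083, and adjusted p = 0.64 with an estimated correlation). An example was Mcm5 (26.6 ± 5.21 against 105 ± 21.3). Without standard morula libraries 1 and 2, the log2 changes were -3.13 for Mcm2 and -3.65 for Twnk, from -3.93 and -4.30. The stage position was 0.684 ± 0.0119 (SD, n = 4) against 0.334 ± 0.0568 (SD, n = 6), a difference of 0.35 (exact p = 0.0048, adjusted p = 0.026).

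Libraries without pyruvate were split so that the effects of inhibitor and absent pyruvate shared none. Over 20 halvings and 16031 genes, the Spearman rho between the effects was -0.304 (SD 0.0722 over halvings), and 32% of genes moved the same way in both. Median-ratio scaling gave -0.318 and 39.7%, and quantile scaling -0.294 and 40.2%. Genes are not independent replicates. An offset shared by libraries without pyruvate would also lower both values, and no standard group had inhibitor, so reversal was untested. Simulated unchanged groups gave 0.0015 and 50.1%. Of a mean of 3742 genes that rose without pyruvate, 92.6% were lower with the inhibitor and 68.2% below the median of all genes. Of a mean of 736 that fell, 32.3% were higher and 65.8% above that median.

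Blastocysts at 114 h were compared to ask what remains of the effect of absent pyruvate at the end of culture. Nearly all changed genes were higher without pyruvate: 12588 of 14313 genes passed the threshold, 11566 higher and 1022 lower. Higher genes were 91.9% of these, and 51.5%, 55.6% and 49.8% under the 3 scalings. All genes had 1.15 as their median log2 change, and 0.11, 0.13 and 0.04 under them. Because the direction of most genes followed the scaling, the genes named here passed the threshold in the same direction under all 3 scalings, save Myc. Large rises included Sf3a2 (34 ± 19.7 against 1.21 ± 1.63), Abcg1 (a cholesterol exporter, 25.3 ± 11.2 against 0.689 ± 0.571), Rap2b (114 ± 29 against 13.2 ± 10.3) and Kmt2d (a histone methyltransferase, 35.4 ± 11.9 against 3.09 ± 2.21). Large falls included Hist1h2an (a histone, 0.987 ± 0.694 against 21.1 ± 7.76), Pigp (354 ± 88.4 against 2370.1 ± 1083) and Tmsb4x (thymosin, 437 ± 115 against 2063 ± 767). DNA replication genes gave all 25 up (camera higher, adjusted p = 0.018, and adjusted p = 0.50 with an estimated correlation). Among them were Fen1 (89.9 ± 8.6 against 16.8 ± 2.68) and Mcm5 (174 ± 14.8 against 49.7 ± 3.51). Of p53 targets, 15 of 16 rose and 1 fell (camera higher, adjusted p = 0.21). These included Cdkn1a (80.3 ± 13.2 against 14.9 ± 5.24) and Plk2 (16.5 ± 5.43 against 1.46 ± 0.73). Ribosome biogenesis gave 29 up and 1 not passed of 30 (camera higher, adjusted p = 0.020, and adjusted p = 0.51 with an estimated correlation). A member was Rrp1b (55 ± 4.7 against 13 ± 1.75). Primitive endoderm genes gave 13 up, 1 down and 3 not passed of 17, against 11 up and 1 down adjusted over the list alone, but the majority turned under median-ratio scaling (3 up, 5 down), under quantile scaling (3 up, 4 down) and with the length trend removed (3 up, 6 down) (camera lower, adjusted p = 0.48, though its median log2 change was 1.13 and its mean 0.96). Examples were Pdgfra (48.2 ± 8.16 against 9.17 ± 3.29) and Gata6 (85.6 ± 11.5 against 20.00 ± 5.49). Ribosomal protein genes were lower, and 32 of 50 fell and 18 did not pass (camera lower, adjusted p = 8.4e-39, and adjusted p = 0.13 with an estimated correlation). Among them was Rpl14 (197 ± 18.9 against 437 ± 87.2). The nuclear-encoded respiratory list was lower too: 30 of 66 fell, 9 rose and 27 did not pass, against 8 up and 26 down adjusted over the list alone (camera lower, adjusted p = 6.3e-31, and adjusted p = 0.13 with an estimated correlation). These included Cox5a (841 ± 105 against 1980.0 ± 242). In glycolysis, 11 of 17 rose, 4 fell and 2 did not pass, but the majority turned under median-ratio scaling (1 up, 9 down), under quantile scaling (3 up, 6 down) and with the length trend removed (0 up, 10 down) (camera lower, adjusted p = 0.018, and adjusted p = 0.20 with an estimated correlation, though its median log2 change was 0.55 and its mean 0.43). Gapdh (60.5 ± 11.3 against 157 ± 30.4) was lower. Trophectoderm genes gave 9 up, 8 down and 4 not passed of 21, but the majority turned under median-ratio scaling (3 up, 14 down), under quantile scaling (5 up, 6 down) and with the length trend removed (2 up, 14 down) (camera lower, adjusted p = 2.2e-05, and adjusted p = 0.13 with an estimated correlation, though its median log2 change was 0.29 and its mean 0.22). Tfap2c (59.5 ± 11.8 against 16 ± 3.43) and Pdp2 (a pyruvate dehydrogenase phosphatase, 340.4 ± 118 against 51.1 ± 17.8) were higher. Myc (51.8 ± 7.98 against 23.4 ± 6.06) was higher, but its log2 change of 1.13 became -0.17 under median-ratio scaling and -0.12 under quantile scaling. These blastocysts lay at 0.75 ± 0.0379 (SD, n = 5) against 1.13 ± 0.0552 (SD, n = 4), a difference of -0.384 (exact p = 0.0079, adjusted p = 0.026) on the stage line, and all 5 were below the standard ones.

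Blastocysts without lactate were compared with standard blastocysts to ask what lactate supports late in culture. The PVA in the column names of the standard blastocysts limits this comparison too. They had lower levels of trophectoderm and primitive endoderm transcripts. Trophectoderm markers gave 14 down, 1 up and 6 not passed of 21 (camera lower, adjusted p = 2.6e-09, and adjusted p = 0.071 with an estimated correlation). Members included Elf5 (a transcription factor of trophoblast stem cells, 3.73 ± 0.717 against 30.7 ± 18.7), Tspan8 (874 ± 189 against 2856 ± 400.3) and Dppa1 (1076 ± 167 against 3016 ± 705). Elf5 lies on chromosome 2, 103411688 to 103450989. Primitive endoderm markers gave 12 down, 1 up and 4 not passed of 17, against 2 up and 13 down adjusted over the list alone (camera lower, adjusted p = 7.8e-08, and adjusted p = 0.28 with an estimated correlation). Examples were Sparc (40.4 ± 7.08 against 164 ± 27.7), Srgn (a proteoglycan, 1.01 ± 0.281 against 21.2 ± 8.65) and Sox7 (0.386 ± 0.238 against 4.25 ± 0.573). Falls were largest in genes such as Slc39a2 (a zinc transporter, 10.1 ± 2.4 against 219.9 ± 118), Gsta1 (a glutathione transferase, 5.93 ± 0.675 against 121 ± 38.3), Unc93a2 (4.98 ± 2.19 against 96.3 ± 24.9), Slc40a1 (0.507 ± 0.0709 against 28.4 ± 26.7) and Plac1 (a placental protein, 33.7 ± 11.4 against 433 ± 102). Slc39a2 lies on chromosome 14, 51892889 to 51896745, Gsta1 on chromosome 9, 78230656 to 78242684 and Plac1 on chromosome X, 53069995 to 53240111. Rises were largest in genes such as mt-Nd3 (471 ± 62.6 against 91 ± 139), Gja1 (connexin 43, 739 ± 256 against 119.9 ± 74.1) and Sod1 (superoxide dismutase, 273 ± 35.4 against 73.6 ± 64.2). Of p53 targets, 10 of 16 rose and 6 did not pass (camera higher, adjusted p = 2.1e-04, and adjusted p = 0.38 with an estimated correlation). Among them were Cdkn1a (39.3 ± 12.9 against 14.9 ± 5.24) and Ccng1 (205 ± 63.6 against 88.1 ± 28). Integrated stress targets gave 6 down, 1 up and 12 not passed of 19, against 1 up and 7 down adjusted over the list alone (camera lower, adjusted p = 2.5e-05, and adjusted p = 0.32 with an estimated correlation). These included Nupr1 (0.753 ± 0.423 against 13.3 ± 6.81), Asns (asparagine synthetase, 69 ± 26.3 against 192 ± 71.9) and Slc7a3 (1.25 ± 0.33 against 12.3 ± 4.87). Mitochondrially encoded mRNAs gave 9 up and 4 not passed of 13, against 12 up and 0 down adjusted over the list alone (camera higher, adjusted p = 3.3e-05, and adjusted p = 0.42 with an estimated correlation), in libraries whose mitochondrial share was the highest of the blastocyst groups. Ldha (5.98 ± 0.301 against 34.9 ± 7.26), Slc2a3 (423 ± 108 against 1296 ± 571) and Mycn (10.04 ± 2.23 against 22 ± 3.02) fell. Slc2a1 (36 ± 6.79 against 13.5 ± 3.53) rose, while 5 of the 11 fixed genes tested did not pass. Mycn lies on chromosome 12, 12936093 to 12941914. Altogether 3330 of 14313 genes passed the threshold, 2001 higher and 1329 lower. Higher genes were 60.1% of these, and 45.5%, 50.3% and 49.6% under the 3 scalings. Leaving out library 2 of this group gave 2086 genes, and no filter on low values 2210. The stage position was 1.11 ± 0.0296 (SD, n = 4) against 1.13 ± 0.0552 (SD, n = 4), a difference of -0.0189 (exact p = 0.57, adjusted p = 0.63).

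Between blastocysts without pyruvate and those without lactate, 12701 of 14313 genes passed the threshold, 11549 higher and 1152 lower. Higher genes were 90.9% of these, and 52.1%, 55.3% and 50.3% under the 3 scalings. All genes had 1.11 as their median log2 change. Trophectoderm genes gave 16 up, 2 down and 3 not passed of 21 (camera lower, adjusted p = 0.98, though its median log2 change was 1.17 and its mean 1.11). Eomes (105 ± 13.5 against 16.6 ± 3.74) and Elf5 (31.1 ± 2.2 against 3.73 ± 0.717) were higher without pyruvate than without lactate. Slc39a2 (151 ± 32.6 against 10.1 ± 2.4), Myc (51.8 ± 7.98 against 14.2 ± 1.88) and Mycn (50.7 ± 6.45 against 10.04 ± 2.23) were also higher. Eomes lies on chromosome 9, 118478212 to 118486132. Mt2 (a metallothionein, 305 ± 55.7 against 1665 ± 448) and mt-Co2 (1066 ± 187 against 5127 ± 461) were lower. Primitive endoderm genes gave 16 up and 1 not passed of 17 (camera higher, adjusted p = 0.083). A member was Serpinh1 (a collagen chaperone, 28.4 ± 6.27 against 1.54 ± 0.72). Ribosomal protein genes gave 45 down, 1 up and 4 not passed of 50 (camera lower, adjusted p = 2.8e-55, and adjusted p = 0.062 with an estimated correlation). An example was Rpl32 (301 ± 59.4 against 1159.8 ± 243).

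Whether the effect of each medium differed between morulae and blastocysts was tested as an interaction, with values as log2 differences of the 2 effects. For pyruvate, 9127 of 16480 genes passed the threshold, 7264 higher and 1863 lower. Higher genes were 79.6% of these, and 39%, 50.2% and 48.5% under the 3 scalings. All genes had 0.63 as their median log2 change, and -0.09, 0.07 and 0.01 under them. Mcm2 (4.22), Tcf7l2 (4.23), Pdp2 (4.16) and Twnk (4.08) had a more upward effect in blastocysts. Mcm2 and Twnk were highest in library 1 of the standard morulae (2651 and 519 CPM). Without standard morula libraries 1 and 2, their differences were 3.41 and 3.43. Glrx (-4.92), Slc40a1 (-4.79), Apoe (-4.68), Cd81 (-4.51) and Ldha (-3.34) had a more downward one. Ribosome biogenesis gave 27 up and 3 not passed of 30, against 28 up and 0 down adjusted over the list alone (camera higher, adjusted p = 6.3e-07, and adjusted p = 0.15 with an estimated correlation). An example was Polr1b (3.02). For lactate, 1555 of 15290 genes passed the threshold, 622 higher and 933 lower. Higher genes were 30.1%, 47.1% and 45.3% under the 3 scalings. Gsta1 (-5.59), Unc93a2 (-4.71), Slc39a2 (-4.64), Plac1 (-4.03) and Nupr1 (-4.21) had a more downward effect in blastocysts. Myc (-2.28), Mycn (-1.53) and Slc2a3 (-2.72) had one as well. Trophectoderm genes gave 11 down and 11 not passed of 22, against 0 up and 12 down adjusted over the list alone (camera lower, adjusted p = 5.0e-08). These included Elf5 (-3.21) and Aqp3 (-2.22). The lactate count was 3184 (1584 higher) without standard morula libraries 1 and 2, and 977 without library 2 of the blastocysts without lactate.

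**Figure D4:**
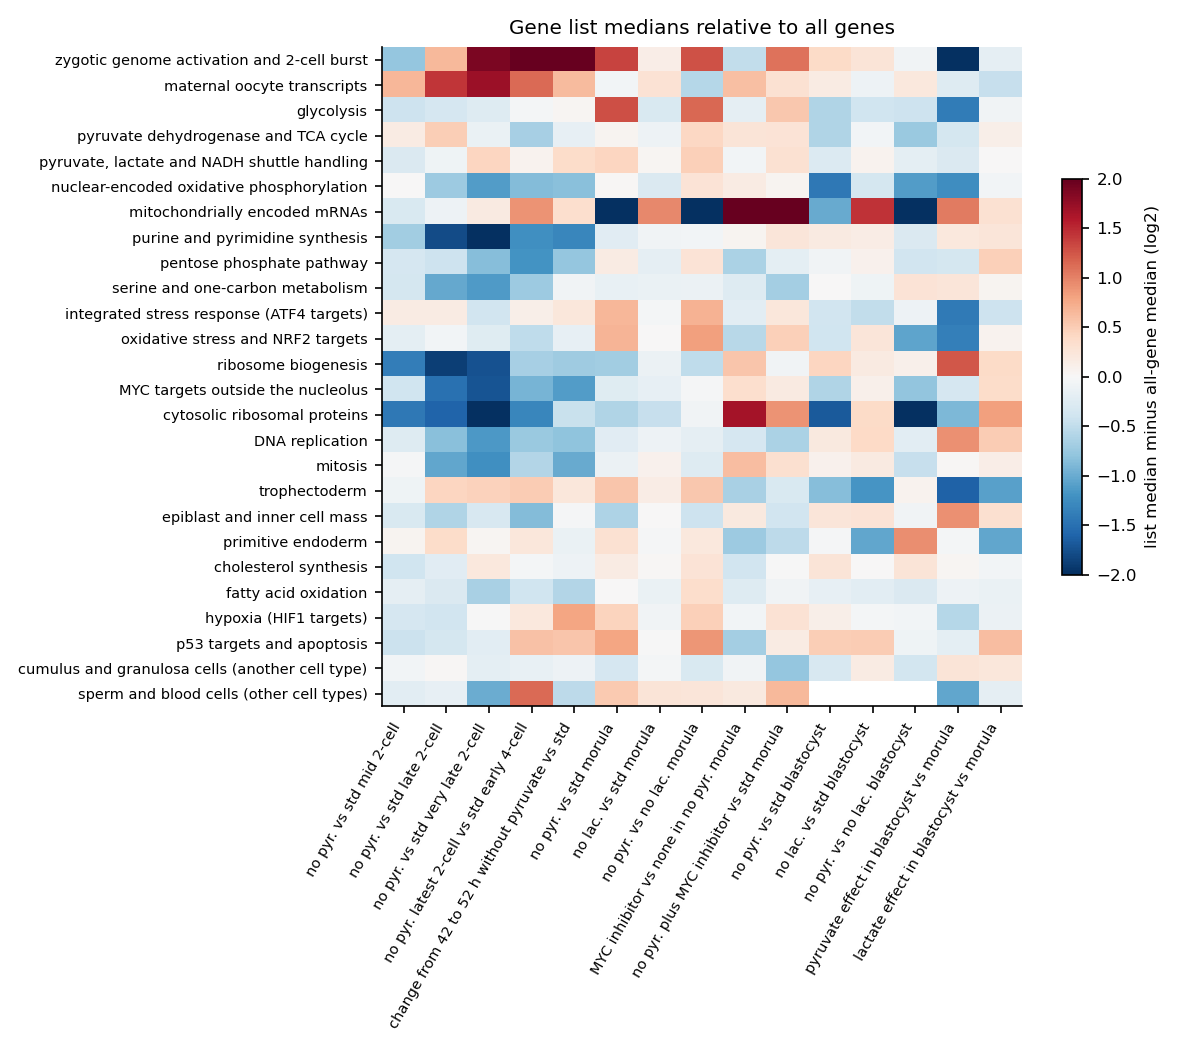
Median log2 change of each gene list minus the median of all genes (colour scale, log2), with lists on the vertical axis and comparisons on the horizontal axis. Trophectoderm genes stood at -1.19 in blastocysts without lactate.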

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

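The tests of slower progress along the standard course, and all uses of scaling, were chosen only after the result was seen. A library lying far from the others of its group was found in 20 of 251 tests, each of 1 measure in 1 group, and chance gives about 1 in 20. Read depth (M reads) was 42.6 in library 4 of early 4-cell embryos (others 27.1 to 28.9), 34.1 in library 3 of standard morulae (others 17.9 to 22.8) and 25 in library 3 of late 2-cell embryos without pyruvate (others 14.9 to 17.6). The share of the 100 highest genes was 23.8% in library 5 of morulae without pyruvate (others 21.1 to 21.7). Levels in CPM that stood apart were, for Myc, 39.99 in library 1 of 16-cell embryos (others 23 to 25.2). For Mycn they were 26.5 in library 3 of standard blastocysts (others 20.1 to 20.7) and 4.61 in library 3 of morulae without lactate (others 2.1 to 2.73), and for Mycl 4.35 in library 2 of late 4-cell embryos (others 0 to 0.389). For Slc2a1 the level was 18.7 in library 4 of standard blastocysts (others 11.1 to 12.4). For Slc2a3 it was 61 in library 1 of early 4-cell embryos (others 20.1 to 22.9). Ldha stood at 58.6 in library 3 of mid 2-cell embryos (others 81.8 to 84.5), 71.7 in library 1 of late 2-cell embryos without pyruvate (others 42.7 to 50.1) and 64.6 in library 5 of morulae without pyruvate (others 87.4 to 94.4). Ldhb stood at 1203 in library 1 of late 2-cell embryos without pyruvate (others 1734 to 1899.9) and 1.92 in library 5 of blastocysts without pyruvate (others 0.509 to 0.809). Mpc1 stood at 264 in library 3 of mid 2-cell embryos (others 315 to 321), 659 in library 3 of late 4-cell embryos (others 775 to 782), 529 in library 1 of 16-cell embryos (others 435 to 452), 1099 in library 2 of standard morulae (others 645 to 752) and 940.3 in library 4 of morulae with the inhibitor (others 789 to 812). Differences between effects, tested as interactions, covered 10294 genes for the change from 42 to 52 h, 9127 for pyruvate in blastocysts against morulae and 1555 for lactate.

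Most changed genes were higher in blastocysts without pyruvate than in standard blastocysts. A smaller share for the 100 highest genes would move all others by 0.408 on the log2 scale. This compares with an observed median of 1.16, which argues against it as the whole cause. A set of highest genes 10 times as large would give 1.07 against 1.22, so a share taken by many abundant genes stays open. Medians rose with gene length (rho 0.487), from 0.446 to 1.56 over 5 classes, so length is argued against only as the whole cause. A split of libraries into 2 kinds (Spearman rho 0.39 with the difference between standard morulae and 16-cell embryos) and an earlier stage (rho 0.141 with 32-cell embryos) could each hold in part and stay open. Both values lay between the bounds set for the tests, and the medium itself stays open as untested.

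Most changed genes were lower in morulae without pyruvate when KY-PYR-9 was present. The larger share of the 100 highest genes would give a shift of -0.348, against an observed median of -0.90, which argues against it as the whole cause. A set 10 times as large would give -0.90 against -0.94 and stays open. A candidate explanation is the same split of libraries into 2 kinds. The rho with the change from standard morulae to 16-cell embryos, which share no library with this comparison, was 0.55. It was 0.459 after quantile scaling. Whether that split is of library making or of biology was not told by the labels, and an effect of the compound stays open as untested.

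The 2-cell libraries without pyruvate lay behind standard libraries of the same age, nearest to standard ages of 36.8, 42.3, 44.8 and 51 h at 42, 48, 52 and 55 h. At 52 h, the only age tested, a mix of embryos held at 34 h and others on time is argued against. Of 182 genes with a standard peak at 42 h, 94.5% exceeded their standard levels at both 34 and 52 h. At 42 and 48 h, distance from the standard course was 0.928 times the largest of left-out standard libraries (0.777 to 1.04). Those of 34 to 48 h reached 0.608, so delay alone is not shown. At 52 and 55 h the ratio was 1.47 (1.29 to 1.89), but standard libraries gauge it only near their own ages. Delay alone and a change beyond it stay open.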

How the results depend on the processing

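The scalings, and leaving out standard morula libraries 1 and 2 or a late 8-cell library, were chosen only after the data were seen. Planned for counts and not run were TMM against median-ratio size factors, a negative binomial test, and a count filter. A pseudocount of 0.1, only the groups compared and a replicate block moved no count of the 18 comparisons by over 1.5 times. With only the groups compared, which was tried for the steps after the data were seen, counts became 219 from late 4-cell to early 8-cell, 163 from early to late 8-cell, 3 to the morula and 7242 from 16-cell to 32-cell. No filter gave 2210 genes for no-lactate blastocysts. Replicate numbers did not pair libraries (no comparison had every pair above 0.1). The replicate block gave 1571 genes for no-lactate morulae, 2659 for no-lactate blastocysts and 1174 for the lactate interaction. Median-ratio, quantile and length settings gave 8047, 6942 and 7144 genes for no-pyruvate blastocysts. They gave 7628, 6761 and 7118 between the blastocyst media. For the inhibitor, quantile scaling gave 7190 and length removal 7384. Without standard morula libraries 1 and 2, 3102 genes changed without lactate and 3184 in the lactate interaction. The rho for the inhibitor was -0.398 over genes called on the libraries not used for the effect. An estimated correlation left 19 list calls. Myc in no-pyruvate blastocysts turned to -0.17 under median-ratio scaling and -0.12 under quantile scaling. The cause was not tested.

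Leaving out 1 library gave 13599 to 13891 for late against early 2-cell, 13646 to 14046 for early 8-cell against late 2-cell, 11750 to 11932 for blastocyst against early 8-cell and 6644 to 7585 for mid 2-cell (no-pyruvate against standard from here on). It gave 10576 to 11621 for late 2-cell, 12053 to 12776 for very late 2-cell, 10832 to 11942 for latest 2-cell, 9498 to 10076 for the 42 to 52 h change and 5622 to 6443 for no-pyruvate morulae. Then it gave 1262 to 2756 for no-lactate morulae, 6080 to 6448 for the morula media, 11404 to 12005 for the inhibitor and 8538 to 9984 for the inhibitor against standard morulae. Last came 12164 to 12523 for no-pyruvate blastocysts, 2086 to 4465 for no-lactate blastocysts, 12339 to 12597 for the blastocyst media, 8220 to 9789 for the pyruvate interaction and 977 to 2285 for the lactate interaction. The counts of 2086 and 977 came without library 2 of the no-lactate blastocysts, the only library here to move them by over 1.5 times. For the steps in order, the ranges were 8802 to 9863, 10765 to 11509, 5572 to 5958, 7624 to 8824, 7476 to 7752, 1102 to 1500, 618 to 1406, 79 to 746, 6850 to 7792, 3319 to 3794 and 7597 to 8073. Counts were 954 without late 8-cell library 1, and 618 and 79 without library 2. In these fits the lone library was assumed to vary like the other groups. Stage differences ranged -0.215 to -0.195, -0.358 to -0.332, -0.358 to -0.352 and -0.192 to -0.165 for 42, 48, 52 and 55 h. They ranged -0.025 to 0.0643 for no-pyruvate morulae (reversed to -0.0086 without library 4 and -0.025 without library 5) and -0.101 to -0.0712 for no-lactate morulae. For the inhibitor against none and standard they ranged 0.286 to 0.375 and 0.34 to 0.37. They ranged -0.409 to -0.365 and -0.044 to -9.3e-05 for no-pyruvate and no-lactate blastocysts. The rho for the inhibitor ranged -0.317 to -0.282. The cause was not tested. At 1 CPM the shallowest library held about 10.2 reads of a gene, so levels below that are not resolved.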

Other observations

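The tests of 2-cell embryos among the morulae and of development held back without lactate were chosen only after the result was seen. Levels in CPM (mean ± SD) of the lactate dehydrogenase genes in standard medium stood apart by stage. Ldhb was at 3183 ± 289.5 in early 2-cell embryos, 279.8 ± 13.6 in late 2-cell embryos, 5.44 ± 0.462 in early 8-cell embryos and 0.237 ± 0.128 in blastocysts. Ldha was at 2.89 ± 0.278, 65 ± 6.47, 17.6 ± 5.53 and 34.9 ± 7.26 in the same groups. The glucose transporter Slc2a3 was at 30.6 ± 3.97 in late 2-cell embryos and 1296 ± 571 in blastocysts.

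A hypothesis for the 2-cell transcripts found in morulae without pyruvate was that 2-cell embryos were among them. The 25 list members that were higher would need 12% of 2-cell RNA. Over 22 transcripts abundant in 2-cell embryos without pyruvate at 55 h, the observed rise was a median of 0.0292 of the rise needed (upper quartile 0.151). Older 2-cell embryos were not measured and could have lost these transcripts, so it stays open. A second hypothesis, that trophectoderm genes were lower without lactate because development was held back, stays open. Stage position differed by -0.0189 (SE 0.0313), but that line ends at the 32-cell stage and measures little of the time after it. The rho of the change with the difference of 32-cell embryos from standard blastocysts was 0.421 after quantile scaling, as a mean over halvings in which they shared no standard library. What else lowers them was not tested.

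Genes called were counted again with the libraries of each comparison split at random into groups of the same sizes, using only the groups compared. In each case 1 split, the real one, called as many. The real split and the highest other gave 13846 and 0 for late against early 2-cell and 12746 and 0 for early 8-cell against late 2-cell. They gave 7169 and 0 for very late against late 2-cell. Here 10 splits are too few for a share under 0.05. The rest were under it, unadjusted. With 35 splits the values were 10430 and 0, 8663 and 0, 11971 and 0 and 8264 and 0 for blastocyst against early 8-cell and for no pyruvate at 42, 52 and 55 h. They were 2389 and 470 for no-lactate blastocysts. With 56 they were 12689 and 0 at 48 h. With 100 drawn they were 1440 and 0 for no-lactate morulae and 6900 and 0 between the morula media. Other splits also called genes in some comparisons: 10838 and 7636 for the 42 to 52 h change and 4405 and 2885 for no-pyruvate morulae. For the inhibitor against none and standard they gave 11916 and 8724 and 9018 and 4809. They gave 12402 and 9971 for no-pyruvate blastocysts, 12786 and 10740 between the blastocyst media, and 9126 and 2999 and 1554 and 483 for the pyruvate and lactate interactions. The steps gave 11107 and 5834, 12786 and 0, 6384 and 1548, 5666 and 0, 219 and 1, 6670 and 4501, 7241 and 4129 and 8672 and 0. These are in order of age without that from late to very late 2-cell and those with the late 8-cell libraries.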
